A study of Camponotus floridanus with 64 samples.

How the data were processed

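Poly(A) RNA was sequenced from central brains of the carpenter ant Camponotus floridanus, per the labels. The series has 64 samples. The 37 RNA libraries stand in 3 tables and are analysed here, and the 27 chromatin immunoprecipitation and input samples, which include whole larvae, are not analysed here. The first table holds 21 scout brains, the second 10 brains of workers on day 1 of adult life, and the third 6 libraries made from subsamples of a single day 1 minor brain. No value column was left without a sample or group.

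Reads were handled with bcl2fastq 2.0, Bowtie2 and Cufflinks 2.2.1, per the submitters' processing notes. The genome build, the annotation and the settings are not given in the sources used here. Scout libraries were made from 15% of a brain and went through 1 round of LinDA, a linear amplification, per the labels' protocols. A spike-in RNA mix was added to the aliquots, per the labels' protocols, and the tables analysed hold no spike-in rows.

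The deposited values are on a log2 scale, with the base inferred here. Raised to the power of 2 and reduced by 1, the numbered identifiers of a day 1 library sum to 8.55e+04 to 7.277e+05. With a natural logarithm the sums reach 2.273e+08 on day 1 and 1.216e+09 in the subsamples. Depth is unknown, because the tables hold no counts.

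Within a table, the deposited log2 values of every library were found to follow 1 shared distribution plus 1 constant per library, with values under 0 set to 0. The largest deviation from that form was 1.00002e-10 in the day 1 and scout tables. The shape is that of quantile normalization followed by a shift. No header or label used here records either step. The constants ran from -0.330 to 0.907 in scouts and from -0.0150 to 0.0288 on day 1.

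Identifiers tied at the bottom of a library had been spread over rising values in the order of the table's lines. This made the tied identifiers recoverable, and an identifier is called detected here where it lay above the tie. A tied value can be a failed estimate as well as an absent transcript. In scouts an undetected identifier carried a deposited value of up to 1.30. On 8 simulated libraries of 6000 identifiers the recovery missed by at most 409, in a library with a negative constant and no visible run, where detection is then a lower bound. Levels given as "listed at 0" and single-library values have the constant removed and undetected identifiers set to 0. Means, differences and tests use the values as deposited unless said otherwise.

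The planned design assumed linear values and log2(value + 1). Since the values were already logged, the tests ran on them directly, and pseudocount alternatives used the back-transformed values. The tests were fitted with limma 3.58.1 in R 4.3.3, with a trend in the variance and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. Genes with a mean deposited value of at least 1, which is log2 of 1 + 1, were tested. The 3 scout groups shared 1 fit of 4899 genes, and the day 1 castes had a fit of 3694 genes in their own table. Tables were normalized separately, so no test crosses them. Gene sets were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation. Comparisons of a single value per library used exact permutation tests in scipy 1.17.1, two-sided. Other tools were numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

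On simulated data built from these libraries, with 50 genes changed at each size, limma recovered 84% of genes changed by 2 on the log2 scale in TSA against DMSO, among 4899 genes. It recovered 20% of those changed by 1. For major against minor, among 3694 genes, it recovered 62% and 36%. The sizes were changed together, with 101 calls in simulated TSA against DMSO and 94 in simulated major against minor. A Benjamini-Hochberg threshold is easier to pass with many such calls than where few genes change. In the real TSA against DMSO data Cflo_16200, at a difference of 2.69, did not pass (limma, adjusted p = 0.261). The shares may therefore overstate what could be found in the real libraries.

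The samples, main tests and alternatives were fixed before the data were examined. Tests of the number of identifiers detected, and of how the effect of C646 differed between colonies, were not part of that plan. The alternatives covered pseudocounts of 0.1 and 5, no filter or a mean of at least 5, quantile normalization, array weights, colony as a fixed or random block, replicate number as a block, single colonies or C646 doses, and leaving out each library in turn. Spike-in scaling and count tests could not be run on these values. Alternatives that remove the constants, return undetected identifiers to 0 or leave out doubted libraries were chosen after seeing the data.

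The numbered identifiers carry no gene names, and 0 identifiers matched the reference table of 14020 genes. A few receptor identifiers carry a name, such as Orco and IR25a, and only Orco matched a list planned by name. Of 23 such lists, 0 reached 5 matched genes, so those lists and the genes of the drug targets are not reported. The prefix of an identifier gives its class, and classes were tested in place of the lists, a choice made after the identifiers were seen. The rule for identifiers without names allowed up to 2 rising and 2 falling per comparison. They were the largest changes among called genes and the 5 smallest p-values per direction. Each had a mean deposited value of at least 2.585, which is log2 of 5 + 1, in 1 group. Cflo_08796, called on day 1, is named outside this rule.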

Results

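The libraries addressed whether inhibitors of histone deacetylation and acetylation move gene expression in the brain of minor worker scouts, and how such movement relates to differences between the worker castes. Minor workers are the smaller caste, which does most of the foraging, and majors are larger and forage less. Scouts had been fed sugar water holding the solvent DMSO (5 brains), 50 µM trichostatin A (TSA, 10 brains), or TSA with C646 at 50 µM (4 brains) or 100 µM (2 brains). The labels' protocols give isolation at day 25 to 30 and 45 days of treatment. If feeding began at isolation, brains with both inhibitors, aged 57 to 66 days, were too young for 45 days of it. So were TSA brains aged 68 days. Feeding time may therefore differ between the arms. TSA inhibits histone deacetylases, and C646 inhibits the acetyltransferases CBP and p300. Day 1 majors and minors had 5 brains each, all from colony SB2. A single further day 1 minor gave a 75% subsample without LinDA, 4 subsamples of 4% with LinDA and 1 of 1% with LinDA. Each scout library came from a single brain, per the labels, and each day 1 library is taken here as a separate brain.

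Libraries differed widely in how many of the 18130 identifiers they detected. DMSO scouts detected 8283 ± 571 (SD, n = 5), TSA scouts 9459 ± 1533 (n = 10) and TSA+C646 scouts 8168 ± 2989 (n = 6). The TSA+C646 library 15 detected 2791 and library 16 detected 12032. No difference between TSA and DMSO was shown by an exact permutation test (p = 0.112 in all colonies, p = 0.171 within SB2). Day 1 minors detected 10864 ± 323 (n = 5). Day 1 majors 1 to 3 detected 5459, 6298 and 6528, and majors 4 and 5 detected 10216 and 11768. No difference between castes in this number was shown by an exact permutation test (p = 0.111, adjusted p = 0.224 over 4 such tests). No library was a copy of another: between any 2 libraries of a table r was at most 0.899 over the genes tested in that table. With the constant removed and undetected identifiers at 0, r within a group was at most 0.962 over 2257 genes tested in all tables.

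**Figure D1:**
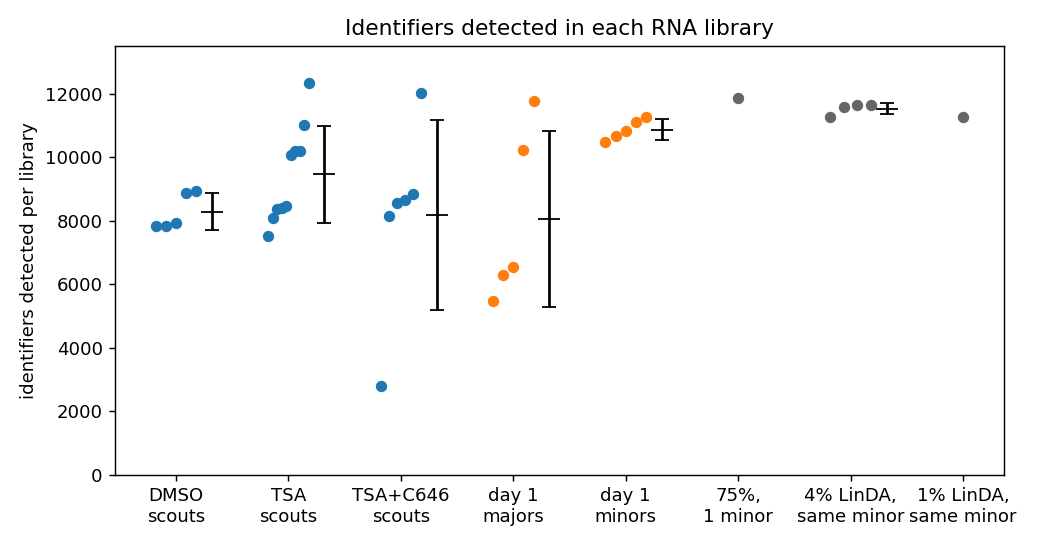
Identifiers detected per library, with 1 point per library and bars for the mean and SD of each group with more than 1 library. Day 1 majors spread from 5459 to 11768, while the 5 minors lie between 10462 and 11259.

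For TSA against DMSO, the comparison that asks what a deacetylase inhibitor does to scout brains, the tested gene with the smallest p was Cflo_16200. It was detected in 10 of 10 TSA brains and in 3 of 5 DMSO brains, at deposited means of 4.25 ± 0.60 and 1.56 ± 1.46. Among the 6 subsamples of a single day 1 minor brain it was detected in 3, at up to 3.51, so a value of 0 in a brain can be a failed estimate. The difference of 2.69 (SE 0.54) did not pass adjustment (limma, Benjamini-Hochberg adjusted p = 0.261), and this gene was named after its values were seen. Cflo_15723 was detected in 7 of 10 TSA brains, at 2.53 to 5.77 where detected, and was listed at 0 in all 5 DMSO brains (limma, adjusted p = 0.995). A transfer RNA identifier, Cflo_tRNA159, was likewise detected in 7 of 10 TSA brains, at 3.74 to 7.95, and listed at 0 in the DMSO brains. Lower in TSA without passing were Cflo_13213, detected in 1 of 10 against 3 of 5 brains, and Cflo_06057, detected in 2 of 10 against 3 of 5.

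No gene passed: limma with Benjamini-Hochberg adjustment called 0 of 4899 genes. At an unadjusted p under 0.05, 133 genes were higher and 27 lower in TSA, beside a median difference over all genes of 0.14. After quantile normalization the numbers were 94 and 93, and the median was -0.02. Array weights called 1 gene, Cflo_16200 (difference 2.80, SE 0.45, limma adjusted p = 0.0208). Within colony SB2 1 gene was called, Cflo_15723, detected in 4 of 4 TSA and 0 of 3 DMSO brains (limma adjusted p = 0.0456). Age differed between the arms, at day 78 in DMSO and days 68 to 73 in TSA, and colonies overlapped only in SB2.

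For TSA+C646 against DMSO, Cflo_16200 stood at 4.42 ± 1.19 (SD, n = 6) against 1.56 ± 1.46 (n = 5), a difference of 2.86 (SE 0.60, limma adjusted p = 0.511). It was detected in all 6 brains given both inhibitors. Cflo_13865 was detected in 5 of 6 against 1 of 5 brains. Cflo_15886, present in all 5 DMSO brains at 3.98 to 4.56, had a mean of 2.32 ± 1.31 with both inhibitors (difference -1.91, SE 0.70, limma adjusted p = 0.999). Library 15 was the only brain without Cflo_15886, and leaving it out gave a difference of -1.45. Cflo_11929 was detected in 1 of 6 against 4 of 5 brains.

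Limma called 0 of 4899 genes in this comparison, and 0 under each other setting run. At an unadjusted p under 0.05, 114 genes were higher and 36 lower. After quantile normalization 82 were higher and 113 lower, and the median over all genes moved from 0.05 to -0.07. Without library 16 the counts were 55 higher and 110 lower, without library 15 they were 169 and 15. The 50 µM dose alone gave 198 and 5, the 100 µM dose, both brains from colony SB4, gave 136 and 481. Library 16, with a constant of 0.907, had the 50 µM dose. Library 15, with a constant of -0.330, was 1 of the 2 brains at 100 µM. A dose effect therefore cannot be told from these libraries. The TSA+C646 brains were aged 57 to 66 days against 78 in DMSO, and the arms shared only colony SB6, with 1 brain each.

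For TSA+C646 against TSA, which asks what the acetyltransferase inhibitor adds, Cflo_11060 and Cflo_00655 were present in all 10 TSA brains and in 5 of 6 brains with both inhibitors, the exception being library 15, which detected the fewest identifiers. Their differences were -1.38 (SE 0.51) and -1.37 (SE 0.45), and neither passed (limma, adjusted p = 0.991 for both). Without library 15 the differences of Cflo_11060 and Cflo_00655 were -0.95 and -0.92, and at 50 µM alone -0.89 and -0.72. Cflo_16586 was detected in 5 of 6 brains with both inhibitors, at 3.23 to 6.40, against 1 of 10 with TSA (limma, adjusted p = 0.801). Cflo_02028 was detected in 4 of 6 against 1 of 10. In DMSO brains these last genes were detected in 2 of 5 and 1 of 5.

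Limma called 0 of 4899 genes here too, and 0 under each other setting run. At an unadjusted p under 0.05, 70 genes were higher and 104 lower, or 129 and 145 after quantile normalization. The direction followed single libraries: without library 16 the counts were 34 and 326, and without library 15 they were 144 and 31. Within colony SB1 they were 216 and 24, and within SB4, where the dose was 100 µM, 30 and 143. Library 16 belongs to SB1 and library 15 to SB4, so colony and dose cannot be told from these libraries. A limma test of the difference between these colonies in the effect of C646 called 0 genes, with 238 at an unadjusted p under 0.05. Ages did not overlap, at 57 to 66 days with both inhibitors and 68 to 73 with TSA, so age is confounded with C646.

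The changes of both treatments against DMSO correlated across genes at r = 0.554, with a covariance of 0.167. Genes are not independent replicates, and both comparisons share the DMSO brains. In 100 simulations of unchanged groups with shared controls the mean r was 0.604 and the covariance 0.224. The simulations gave all groups the same spread per gene. With the constants removed and undetected identifiers at 0, the median SD was 0.40 in DMSO, 0.56 in TSA and 0.71 in TSA+C646 scouts. A control spread set too wide raises the simulated covariance, so the observed values are not read as lower than in unchanged groups. With the DMSO brains split 2 and 3, so that no control was shared, the mean r over 20 splits was -0.0286 (range -0.0814 to 0.0316) and the covariance -0.0145.

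**Figure D2:**
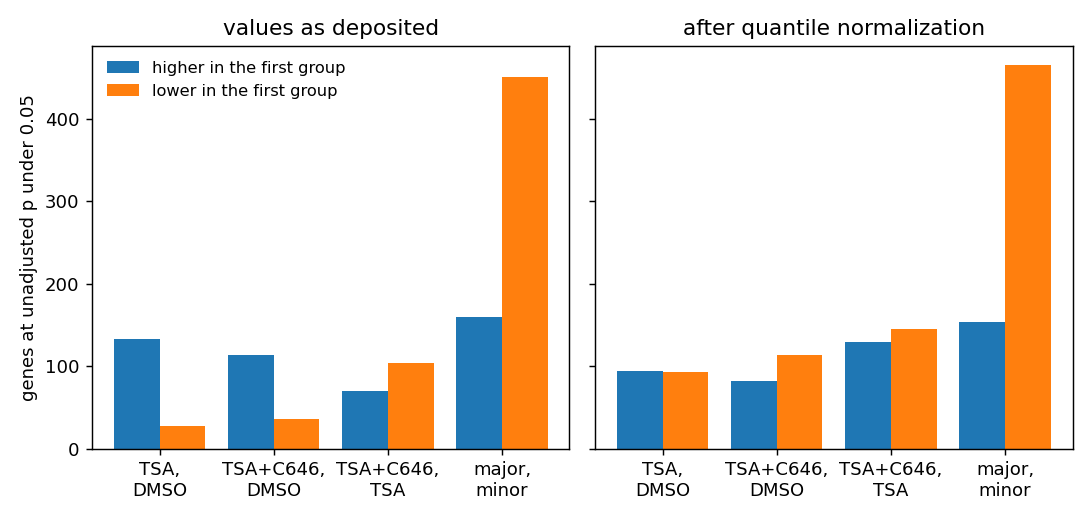
Genes at an unadjusted p under 0.05 in each comparison, as bars for genes higher and lower in the first group named, from the values as deposited (left) and after quantile normalization (right). In TSA against DMSO 133 higher and 27 lower became 94 and 93.

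Majors and minors on day 1 differed in 2 of 3694 genes (limma, Benjamini-Hochberg), both lower in majors. With replicate number as a block 0 genes passed (limma, smallest adjusted p 0.0539, 522 genes at an unadjusted p under 0.05), and 7 of 100 splits of the libraries gave as many calls. Cflo_08796 stood at 3.36 to 3.84 in the 5 minors, at 1.36 and 0.80 in majors 4 and 5, and was listed at 0 in majors 1 to 3 (limma, adjusted p = 0.00328, or 0.0693 with a pseudocount of 0.1). It was also present in all 6 subsamples of the other minor brain, at 3.91 to 4.45. Among the older scouts, which are minors too, Cflo_08796 was detected in 2 of 5 DMSO, 4 of 10 TSA and 3 of 6 TSA+C646 brains, in a table normalized separately, so the levels are not compared. Cflo_00620 stood at 4.32 to 7.35 in the 5 minors and was listed at 0 in all 5 majors (limma, adjusted p = 0.00298). It was listed at 0 in the 1% subsample of the other minor and in 20 of 21 scout brains. Cflo_02786 was listed at 0 in all 5 majors and stood at 1.79 to 5.21 in minors without passing (limma, adjusted p = 0.0687). It passed with a pseudocount of 0.1 (limma, adjusted p = 0.00999), without minor 2 (0.0136), without minor 4 (0.0317) and without major 5 (0.0446).

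Higher in majors without passing were Cflo_14649, at 5.84 ± 1.95 against 1.60 ± 0.79 (SD, n = 5 each), and Cflo_14217, with a difference of 3.88 (SE 0.81; limma, adjusted p = 0.164 for both). In the values as deposited, Cflo_14649 stood at 7.21 to 7.30 in majors 1 to 3, the libraries with the fewest genes detected. It stood at 4.08 and 3.37 in majors 4 and 5. Without majors 1 to 3 the differences of Cflo_14649 and Cflo_14217 were 2.13 and 2.05, and without major 5 both passed (limma, adjusted p = 0.0223 and 0.0293). At an unadjusted p under 0.05, 160 genes were higher and 451 lower in majors. Without majors 1 to 3 these were 177 and 174. The 2 calls were then Cflo_08796 and a gene higher in majors, Cflo_10475 (limma, adjusted p = 0.0422 and 3.61e-05), while Cflo_00620 kept its difference of -5.95 with a larger SE of 0.86 (limma, adjusted p = 0.130). Leaving out major 5 gave 37 calls, 6 higher and 31 lower, and leaving out major 4 or minor 5 gave 4.

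**Figure D3:**
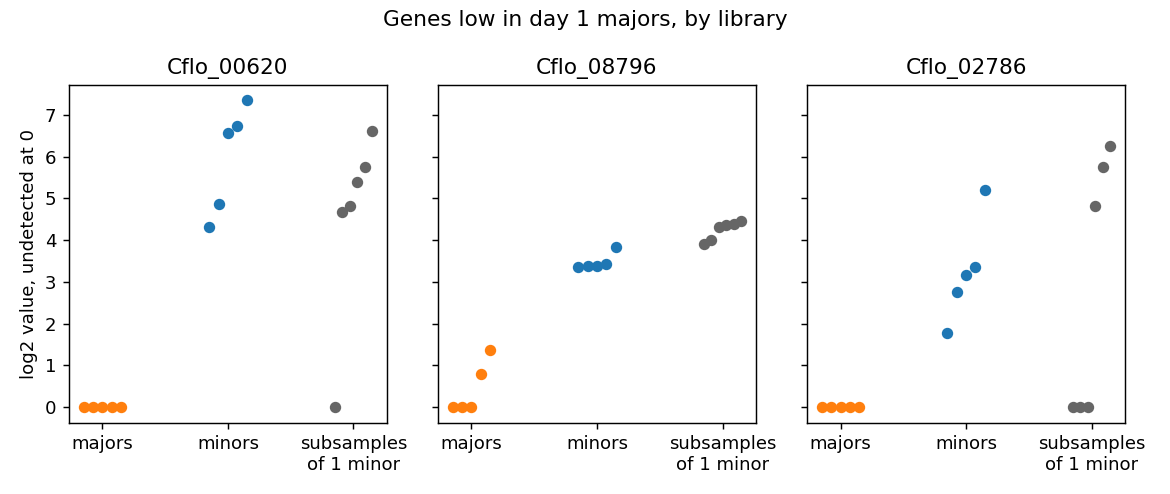
Log2 values of 3 genes by library, with the constant removed and undetected identifiers at 0, for 5 majors, 5 minors and 6 subsamples of another minor. Cflo_08796 is above 3 in every day 1 minor library and subsample, while Cflo_00620 and Cflo_02786 fall to 0 in 1 and 3 of the subsamples.

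Whether genes that differ between castes move with the inhibitors was asked with 2 sets of 200 genes, those with the smallest p in each direction on day 1, since fewer than 20 passed. Of the major-higher set 136 genes and of the minor-higher set 139 were tested in scouts. In TSA against DMSO the major-higher set had a median difference of 0.11 and the minor-higher set 0.14, against 0.14 for all genes (camera, preset correlation, p = 0.487 and p = 0.839). With C646 added to TSA the medians were -0.12 and -0.11, against -0.10 for all genes (camera, preset correlation, p = 0.772 and p = 0.486). With an estimated correlation the 4 p-values were 0.792, 0.956, 0.912 and 0.850. Across 2388 genes the caste difference correlated with the TSA difference at r = -0.0870 and with the added C646 difference at r = 0.0395. Sets made without majors 1 to 3 gave p = 0.464 and p = 0.544 in TSA against DMSO (camera, preset correlation). With C646 added to TSA they gave p = 0.991 and p = 0.349 (camera, preset correlation). No caste set was shown to move, and the sets are picks by rank, not established caste genes.

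Subsamples of a single minor brain gave the technical error. The 4 LinDA libraries from 4% of the brain correlated with the unamplified 75% library at a mean r of 0.886 ± 0.009 (SD, n = 4) across 8462 genes, and with each other at 0.890. The 1% library correlated with the 75% library at 0.876. The 75% library detected 11848 identifiers, the 4% libraries 11529 ± 181 and the 1% library 11252. Of genes at a level of 0 to 1 in the 75% library the 4% libraries missed 19.4% ± 2.1, at 2 to 4 they missed 2.48% ± 0.21, and over 6 they missed 2.65% ± 0.67. Over 2257 genes tested in all tables, the median SD was taken with the constant removed and undetected identifiers at 0. It was 0.14 between 4% subsamples, 0.30 between minor brains and 0.69 between major brains. Among scouts it was 0.40 with DMSO, 0.56 with TSA and 0.71 with TSA+C646, with tables normalized separately. Genes that a library failed to detect can add to these SDs, as in majors 1 to 3 and TSA+C646 library 15. Failed detection and differences between animals are not separated here.

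**Figure D4:**
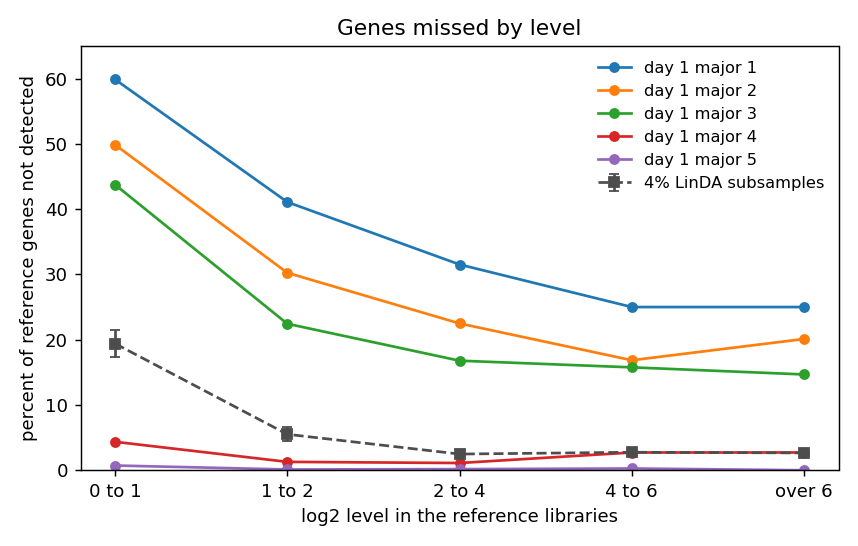
Percent of genes not detected, by log2 level in the reference libraries: genes detected in all 5 minors for each major, and genes of the 75% subsample for the 4% LinDA subsamples (mean and SD of 4). Majors 1 to 3 missed 59.9%, 49.9% and 43.7% of genes at a level of 0 to 1, and 25.0%, 20.1% and 14.7% over 6.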

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

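Of the tests in this part, all were chosen after the result was seen except the alternatives fixed before the data were examined.

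Majors 1 to 3 detected fewer genes than the other day 1 libraries. Caste stays open: 4 of 5 majors detected fewer identifiers than every minor, while major 5 detected 11768, more than any minor. A low yield of these 3 libraries fits the dependence on level: they missed 51.2% of genes at a level of 0 to 1 in the minors and 19.9% over 6. Genes that are abundant in minors and still listed at 0 may be failed estimates, and why the missed share levels off at 4 and above was not tested.

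In TSA against DMSO most genes at an unadjusted p under 0.05 were higher. With all libraries 133 were higher and 27 lower (83.1% higher). Without the 4 libraries with the largest constants in absolute size 145 were higher and 86 lower (62.8%). These were TSA libraries 9 and 10 and TSA+C646 libraries 15 and 16. The latter are in neither group compared and enter only the shared estimate of spread, so leaving them out can change the number of genes at this p. The share fell because more genes were lower and not because fewer were higher. Leaving out these libraries therefore does not decide the part of the constants. Mean constants were 0.152 in TSA and -0.014 in DMSO scouts. With the constants removed and undetected identifiers at 0, 92 were higher and 80 lower (53.5%), at a median difference of -0.02. The excess thus went with the constants, whatever their origin. Quantile normalization and removal of the constants take out a shift common to a whole library, whether it is technical or real. They need not balance the directions. In TSA+C646 against DMSO 77 were higher and 127 lower with the constants removed. In major against minor 154 were higher and 465 lower after quantile normalization. They do not decide where the constants come from. Within SB2 208 were higher and 72 lower (74.3%), so the excess was also present within 1 colony, with too few libraries to set a spread on it. The SB2 TSA brains include library 10, with a constant of 0.840. Treatment and age are untested. Whether the constants themselves come from spike-in scaling, from the number of genes detected or from the treatment stays open, as no source used here describes them.

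For Cflo_08796, lower in majors, majors 4 and 5 also differed from the minors, by -2.37, so the difference does not rest on majors 1 to 3 alone. The gene was picked with majors 4 and 5 included, so their values are no independent test of low yield. Detection in 6 of 6 subsamples of the other minor brain argues against on or off switching at few reads in that brain. These libraries detected 11252 to 11848 identifiers, so they cannot show how Cflo_08796 behaves in majors 1 to 3. Among scout brains it was detected in 9 of 21. On or off behaviour of Cflo_08796 in the majors therefore stays open. For Cflo_00620 the difference in majors 4 and 5 was -5.95, with the same limit. On or off behaviour of Cflo_00620 at few reads remains open, since only 5 of 6 subsamples of a single minor brain held it. A caste difference in Cflo_08796 on day 1 is therefore a hypothesis that these tests leave standing, and chance could not be excluded for the pair, as given next.

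Of 100 splits of the 10 day 1 libraries, 7 gave 2 or more calls, the real one included, and the highest of the others gave 6, so chance cannot be excluded for the calls. Of the same splits 1, the real one, gave 611 genes at an unadjusted p under 0.05, and the highest other gave 526. That other split kept majors 1 to 3 on the same side, and the highest with them apart gave 300. Keeping these majors together also keeps most of the caste together, so these splits do not separate caste from yield. Without majors 1 to 3, 177 genes were higher and 174 lower, so the excess of lower genes was seen only with these libraries included, with 2 majors left to judge by. With 0 calls in the scouts every split, 100 of 100, gives as many by definition, which decides nothing. The highest other splits gave 7, 5 and 6 calls for TSA against DMSO, TSA+C646 against DMSO and TSA+C646 against TSA. At an unadjusted p under 0.05 the real counts of 160, 150 and 174 were met by 25, 85 and 75 of 100 splits, with highest others of 739, 474 and 1031. The medians of the other splits were 124, 263 and 212 in the same order. Why some splits gave several times the real number was not tested. For the caste sets, 37 and 87 of 100 splits gave as small a p in TSA against DMSO and 81 and 53 in TSA+C646 against TSA, with smallest other p-values of 0.0506, 0.0016, 0.0114 and 0.00055.

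Single libraries stood apart from the rest of their group in 8 of 51 sets of values tested, where about 1 in 20 would by chance for normally distributed values. That rate does not hold for genes that are on or off, where 1 detected library among values near 0 is flagged. The excess is therefore not read as a count of aberrant libraries. Gene values here are as deposited, constants included. The constant of TSA+C646 library 16 was 0.907, against at most 0.0176 in the other 5. A 4% subsample detected 11259 identifiers, against at least 11584 in the other 3. Major 5 detected 79 odorant receptors, against at most 32 in the other majors. Minor 4 had 3.84 for Cflo_08796, against at most 3.43 in the other minors. Cflo_11929 was at 4.30 in TSA+C646 library 16, Cflo_13213 at 4.31 in TSA library 10, Cflo_13865 at 3.30 in DMSO library 17 and Cflo_16586 at 2.02 in TSA library 3, each against less than 1 in the rest of the group.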

How the results depend on the processing

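Settings that remove the constants, return undetected identifiers to 0 or leave out doubted libraries were chosen after seeing the data. The 0 calls in TSA+C646 against DMSO and against TSA held under every setting run. In TSA against DMSO array weights, array weights with the constants removed, and SB2 alone each gave 1 call, the last being Cflo_15723 (4.08), and the other settings gave 0. In major against minor the calls were 1 with a mean of at least 5 and between 2 and 37 on leaving out each library. The cause was not tested. Cflo_08796 was not tested with that filter, as the mean of its deposited log2 values lay under 2.585. It missed the threshold with a pseudocount of 0.1 (limma, adjusted p = 0.0693, range over its settings 0.00162 to 0.0693). Day 1 replicate numbers are shared by the castes but nothing says that they pair brains: with the replicate block there were 0 calls (limma, smallest adjusted p 0.0539, 522 genes at an unadjusted p under 0.05). Deviations of same-numbered brains correlated at -0.12 to 0.17, and 1 of 5 majors correlated best with the minor of its number. With colony as a fixed block the direction reversed for the major-higher set in TSA against DMSO (p = 0.752) and the minor-higher set in TSA+C646 against TSA (p = 0.566) and against DMSO (p = 0.150). The minor-higher set in TSA against DMSO reversed with quantile normalization (p = 0.728) and with the constants removed (p = 0.719). None of these sets passed in either direction, and sets of 200 genes were already in use. The r of both treatments was -0.0286 with split controls, which share no brain, and 0.596 with a pseudocount of 0.1. The subsample agreement was 0.802 with a pseudocount of 0.1, 0.933 with no filter and 0.851 by Spearman's rho. Among identifier classes, ribosomal RNA in TSA+C646 against DMSO reversed with the constants removed (adjusted p = 0.369) and with colony (adjusted p = 0.565), and transfer RNA with the constants removed (adjusted p = 0.369). Depth is unknown, so precision rests on the spread between brains.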

Other observations

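Chemoreceptor genes were among the few classes that the identifiers name, and the tests in this part were chosen after the result was seen, except those of receptors as a share of detected genes and of non-overlapping genes, whose outcome had not been seen. Of 407 odorant receptor identifiers, which serve smell in the antenna, DMSO scout brains detected 48.8 ± 11.7 (SD, n = 5), TSA brains 71.2 ± 36.8 (n = 10) and TSA+C646 brains 65.7 ± 45.7 (n = 6). Day 1 minors detected 52.6 ± 10.3 and majors 32.6 ± 27.1 (n = 5 each). Across the 21 scouts 0 receptors were detected in every brain and 22 in at least 50% of them, while 95 were detected in none. The co-receptor Orco was detected in 11 of 21 scout brains, at no more than 0.94. TSA library 10 and TSA+C646 library 16 detected 154 and 150 receptors, the 2 libraries with the most genes detected among scouts. Receptors were a mean of 0.586% of the genes detected in DMSO, 0.722% in TSA and 0.736% in TSA+C646 brains, and 1.25% in each of these 2 libraries, which had the highest counts. By exact permutation tests no difference between TSA and DMSO was shown in the number of receptors (p = 0.200) or in their share of genes detected (p = 0.294), so the part played by the total number of genes is left open.

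Of 6 named receptor identifiers looked at, the ionotropic IR25a was the only one detected in all 10 day 1 brains. With the constant removed and undetected identifiers at 0, it stood at 1.33 ± 0.18 in minors and 1.13 ± 0.34 in majors. Transfer RNA identifiers had a median difference of 0.80 in TSA against DMSO and -0.71 in TSA+C646 against TSA. The second passed with the preset correlation (camera, adjusted p = 0.0478) and not with an estimated one (adjusted p = 0.745). It also did not pass with colony as a block (adjusted p = 0.116) or with the constants removed (adjusted p = 0.0754). The first passed only with the constants removed (adjusted p = 0.00234, against 0.741 with an estimated correlation and the deposited values). Small nuclear RNA identifiers, with a median of -0.71, passed in TSA+C646 against TSA with the preset correlation (camera, adjusted p = 0.0478). They did not pass with an estimated one (adjusted p = 0.244), with colony as a block (adjusted p = 0.0593) or with the constants removed (adjusted p = 0.0754). The libraries are of poly(A) RNA, and how well they measure transfer and small nuclear RNA was not tested.

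Cflo_16200 was the only tested gene for which all 16 brains given an inhibitor lay above all 5 DMSO brains, at 3.10 to 7.02 against at most 3.02, and 0 genes lay below in all 16. Chance gives 0.482 such genes among 4899. Of 100 splits of the 21 scouts into 16 and 5, 35 gave at least 1, and the highest other gave 24, so chance is not excluded. Cflo_15723 was detected in 10 of 16 brains given an inhibitor, in 0 of 5 DMSO brains and in 0 of 16 day 1 libraries. Fisher's exact test gave p = 0.0351 for the scouts, with no adjustment for having been picked. It was listed at 0 in all 4 brains of colony SB4. Genes detected in at least 10 inhibitor brains and in no DMSO brain numbered 41. Of 100 splits 26 gave as many, and the highest other gave 151.

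Some genes were on or off between subsamples of the same brain. Of 2032 identifiers that reached a value of 4 in a subsample of the single minor brain, 225 (11.1%) were listed at 0 in at least 1 of its other subsamples. They were 71 of 4745 scout genes and 65 of 3546 day 1 genes compared. Among all genes at an unadjusted p under 0.05 they were 5 of 152 in TSA against DMSO, 3 of 149 in TSA+C646 against DMSO, 10 of 166 in TSA+C646 against TSA and 20 of 600 in major against minor. Among genes at an unadjusted p under 0.05 with a difference of at least 2, a limit that itself favours such genes, they were 3 of 15, 3 of 17, 7 of 16 and 16 of 134 in the same order. Genes that stayed under 4 in that brain could not be classed. On day 1, 13 genes were detected in all 5 minors and no major, and 3 in all 5 majors and no minor. Of 100 splits 6 gave as many as 16 such genes, and the highest other gave 52.

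Colony could be compared within 1 treatment only in TSA scouts, with 4 brains each of SB1 and SB2, whose ages also differed. Limma called 0 of 4899 genes, with 42 higher and 158 lower in SB1 at an unadjusted p under 0.05, or 106 and 142 with the constants removed. Of the 35 splits 16 gave as many as 200, and the highest other gave 639.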
